A study of Homo sapiens with 9 samples.

How the data were processed

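The series measured gene expression in what the labels give as ovarian cancer cells and in cisplatin-resistant lines of the same name. The identity of the cells was not tested here. Per the labels, 9 libraries fall into 3 groups of 3: OV90, given as sensitive, and OV90CisR1 and OV90CisR2, given as resistant and kept in medium that contained cisplatin. Per the labels' protocols, RNA was isolated with Trizol, libraries were made with a QuantSeq kit, which reads the 3' end of messenger RNA, and they were sequenced single-end on a NextSeq 550. Nothing in the labels says whether the replicates were separate cultures, so p-values measure the spread between these samples only, which may be technical.

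The authors deposited 1 table of normalised values for 43424 gene symbols, a signal on a scale of reads. Per the submitters' processing notes, Bowtie2, bedtools and edgeR were used and the genome build was GRCh38. Versions, annotation, counting rules and strand handling are not given in the sources used here. Within each column, 100% of the values above 0 were whole multiples of the smallest value, with a tolerance of 1e-06, so each deposited value is a whole read count divided by 1 factor per library. These factors equalled median-of-ratios size factors computed from the recovered reads. The recovered read totals were 6187238, 6427647 and 7594704 for OV90 replicates 1 to 3, 6211177, 6096939 and 5825708 for OV90CisR1 replicates 1 to 3, and 6381642, 7607679 and 7520000 for OV90CisR2 replicates 1 to 3. Reads of a 3' kit without molecular identifiers are not independent molecules, so statements on counting error cover counting only. A read count of 3 corresponded to normalised values between 2.62 and 3.37. Genes that share reads with near-identical copies, such as ribosomal protein genes and their pseudogenes, and genes that overlap others are uncertain, because the counting rules are not known.

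Genes were kept when they reached 1 CPM, scaled to the column total, in at least 3 of the 9 libraries, which left 14233 genes. Values were tested as log2(value + 1) with limma 3.58.1 in R 4.3.3, with a variance trend, over all 9 libraries and a mean per group. P-values were adjusted by the Benjamini-Hochberg method and the threshold was 0.05. Fold changes are on the log2(value + 1) scale, which understates changes of genes with low values. Tests of gene lists used camera with a preset correlation of 0.01 on 31 lists, of which 29 had at least 5 tested members. The metallothionein and leukocyte marker lists had 2 each and were not tested as lists. Each list was also tested with an estimated correlation and with fry, a rotation test of whether a list's genes move, on balance, in a common direction. All 954 list entries matched a symbol of the table, 16 of them through an alias.

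The tests, the samples in them, the lists and the rule for named genes were fixed before the data were examined. The rule names a panel of 14 genes where tested. It also names, for each comparison, the 5 largest rises and the 5 largest falls among genes past the threshold, changed at least 2-fold, with groups that did not overlap and a mean above the median of tested genes. From each list described it names up to 2 members that rose most and 2 that fell most past the threshold. For changes shared by both resistant lines it names the 5 rises and the 5 falls with the largest smaller fold change and a mean above the median. Some genes that the rule names are not reported here. Coordinates are those of RefSeq genes on GRCh38.p14, which held 14085 of the 14233 tested symbols. GC content was taken from the last 100 bases of the longest GENCODE protein-coding transcript with an annotated 3' UTR, available for 11730 tested genes, or 82.4%.

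The procedure was tested on simulated data with 100 genes changed 2-fold, 100 changed 4-fold and 14003 unchanged genes. For OV90CisR1 against OV90, 45 of the 2-fold and 87 of the 4-fold changes were recovered and 8 unchanged genes were called. For OV90CisR2 against OV90 the numbers were 42, 79 and 11. For OV90CisR2 against OV90CisR1 they were 33, 78 and 8. The remaining simulated genes formed a list with a smaller rise. Simulated genes varied independently, without shifts of whole libraries such as those reported below for OV90 replicate 3 and OV90CisR1 replicate 3. The numbers describe that setting only.

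The alternatives were other pseudocounts (0.1 and 5), other filters, quantile and TMM scaling, fits on the groups compared only, a replicate block, each library left out in turn, robust and untrended variance estimates, edgeR 4.0.16 quasi-likelihood and DESeq2 1.42.0 tests on the recovered reads, array quality weights, removal of the trend with GC content, and omission of 2 libraries that stood apart. TMM scaling, the quality weights, the GC trend and the omission of these 2 libraries were chosen after seeing the data.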

Results

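Messenger RNA was profiled by 3' end sequencing in OV90, per the labels a line of ovarian cancer cells, and in OV90CisR1 and OV90CisR2, lines labelled cisplatin-resistant and kept in medium with cisplatin, with 3 libraries per group. The effects of resistance and of exposure to the drug were therefore not separable. The identity of the cells was taken from the labels and not tested, and PAX8 and MUC16, markers of ovarian carcinoma, had 0 reads in OV90. The series title names epithelial-mesenchymal transition as the route to resistance under study. The libraries held between 5825708 and 7607679 recovered reads and between 17761 and 19153 genes above 0. Mitochondrially encoded genes took 14.9% ± 1.5 (SD, n = 3) of the signal in OV90, 17.6% ± 1.1 (SD, n = 3) in OV90CisR1 and 16.9% ± 0.29 (SD, n = 3) in OV90CisR2. Pearson correlations of log2 values were 0.979, 0.980 and from 0.978 to 0.982 between the closest libraries of OV90, OV90CisR1 and OV90CisR2. OV90 replicate 3 correlated with the other OV90 libraries at 0.955 and 0.957, and OV90CisR1 replicate 3 with its group at 0.941 and 0.942. Against the other OV90 libraries, OV90 replicate 3 had a median log2 difference of -1.13 over sterol biosynthesis genes and 0.89 over hypoxia and glycolysis genes. The median was 0.55 over cell cycle genes and -0.65 over interferon-stimulated genes. No pair of replicates agreed within counting noise, the smallest chi-square per degree of freedom being 2.04.

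The first comparison asked how OV90CisR1 differed from OV90. CGA, which encodes the common alpha subunit of glycoprotein hormones (chromosome 6, 87085498 to 87095106), rose from 15.2 ± 14.2 to 2030 ± 257 normalised reads (SD, n = 3), a log2 fold change of 7.69 ± 0.73 (SE; limma adjusted p = 0.00018). OV90 replicates 1, 2 and 3 had 15.4, 29.2 and 0.9 normalised reads of CGA. The size of its fold change in either resistant line therefore depends in part on OV90 replicate 3. FREM2, an extracellular matrix protein (chromosome 13, 38687077 to 38887131), rose from 30.2 ± 9.18 to 778 ± 26.4. ALCAM, a cell adhesion molecule (chromosome 3, 105366909 to 105576900), rose from 89.95 ± 5.72 to 1479 ± 95.2, with a log2 fold change of 4.02 ± 0.14 (limma adjusted p = 8.4e-08). TFPI, an inhibitor of coagulation, rose by 2.27 ± 0.38 on the log2 scale and CRISPLD1 by 2.23 ± 0.32. BEX1 fell from 766 ± 391 to 61.6 ± 15, and S100A10 from 482 ± 64.9 to 62.6 ± 22.7. SPECC1 fell from 299 ± 10.7 to 66.4 ± 3.49, FHL1 from 225 ± 23.8 to 52.6 ± 13.3 and ADD2 from 329 ± 19.8 to 90.2 ± 17.2. In total, 2252 of 14233 genes passed the threshold, of which 1215 rose and 1037 fell. At least 2-fold changes were found for 1020 of them, 588 up and 432 down. The count was 939 without OV90 replicate 1 and 1358 without OV90 replicate 2. It was 771 in a fit of only these 2 groups, 3901 without OV90 replicate 3 and OV90CisR1 replicate 3, and 4220 with quality weights. Without OV90 replicate 1, 565 genes changed at least 2-fold.

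**Figure D1:**
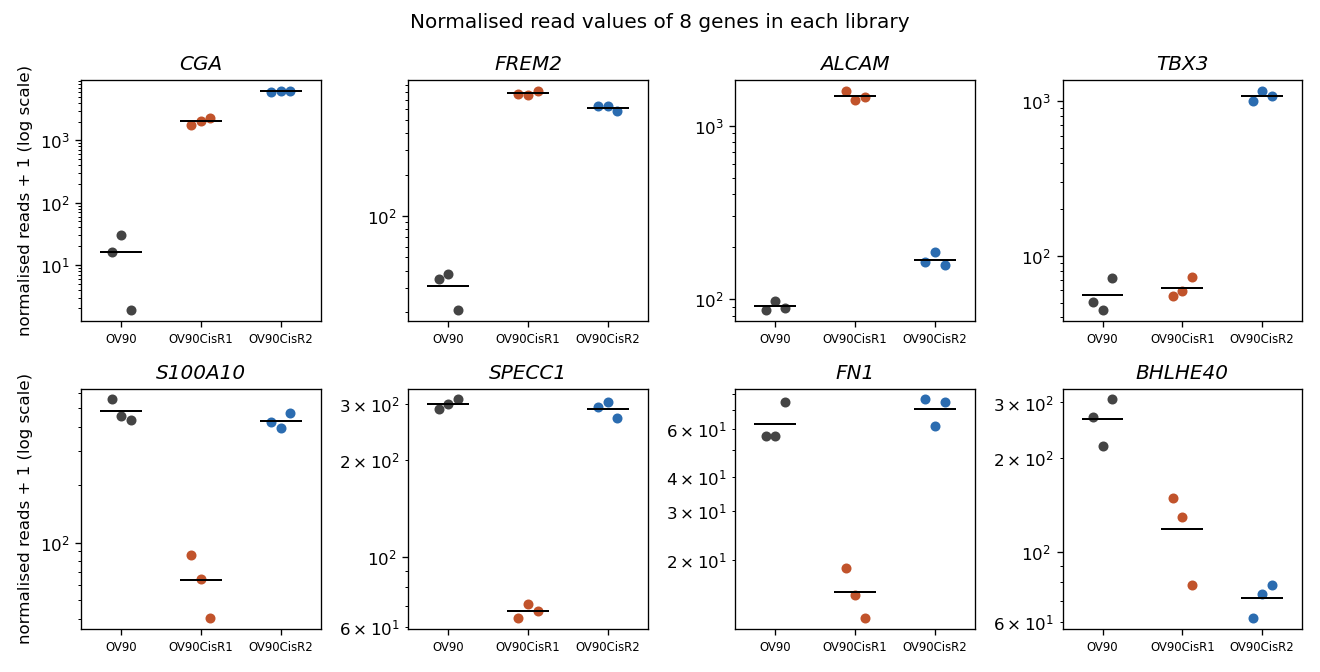
Normalised reads + 1 on a log axis (vertical) for 8 genes in OV90, OV90CisR1 and OV90CisR2 (horizontal); points are the 3 libraries of each group and lines are group means. CGA and FREM2 were higher in both resistant lines than in OV90, ALCAM was highest in OV90CisR1 at 1479, and TBX3 was highest in OV90CisR2 at 1085.

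Markers of epithelial and mesenchymal state moved in different directions in OV90CisR1. FN1, which encodes fibronectin (chromosome 2, 215360865 to 215436068), fell from 61.6 ± 10.5 to 14.2 ± 3.18 normalised reads (SD, n = 3), with a log2 fold change of -2.05 ± 0.26 (SE; limma adjusted p = 0.001). Of 37 tested mesenchymal markers, 6 rose and 5 fell (8 and 6 adjusted over the list alone), and the list was not called by camera (adjusted p = 0.55, and adjusted p = 0.66 with an estimated correlation) but was by fry, up (adjusted p = 0.012). POSTN, the matrix protein periostin, rose from 2.9 ± 0.194, about 3 reads, to 48.2 ± 7.17, and WNT5A from 439 ± 350 to 1255 ± 15.2. ACTA2, smooth muscle actin, fell from 11.2 ± 1.23 to 2.94 ± 3.45. Of 15 tested epithelial markers, 2 rose and 2 fell (2 and 3 adjusted over the list alone; camera adjusted p = 0.93). DSP, a desmosomal protein, rose from 0.667 ± 0.578, under 3 reads, to 4.25 ± 2.06, and MUC1, a membrane mucin, from 129 ± 22.3 to 229.8 ± 36.1. DSG2 fell from 24.6 ± 19.2 to 2.89 ± 1.39 and CD24 from 22.1 ± 11.8 to 3.5 ± 2.55. Of 14 tested transcription factors of the transition, 1 passed (0 adjusted over the list alone, 3 at an unadjusted p under 0.05, and 1 each with edgeR and DESeq2; camera adjusted p = 0.9).

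The calls for DSP and ACTA2 were lost without any library except OV90CisR1 replicate 3 (adjusted p 0.057 to 0.11 and 0.069 to 0.1). That for DSG2 was lost without OV90 replicates 1 or 2, OV90CisR1 replicates 1 or 2 or OV90CisR2 replicate 1 (0.051 to 0.11). CD24 no longer passed without OV90 replicate 1 (0.076) or OV90 replicate 2 (0.059). Without OV90 replicate 1 the adjusted p was 0.052 for WNT5A.

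Of the other genes of the fixed panel, none changed past the threshold in OV90CisR1. VIM, which encodes vimentin, had 36050 ± 3330 normalised reads in OV90 and 20970 ± 9310 in OV90CisR1 (SD, n = 3; limma adjusted p = 0.066), and EPCAM 44.9 ± 6.77 and 50.2 ± 11.6 (0.73). CDH2 had 7.49 ± 2.7 and 4.26 ± 0.897 (0.35), ZEB1 212 ± 76.4 and 168 ± 35.9 (0.49), and AXL 116 ± 15.8 and 145 ± 36.5 (0.33). SLC31A1, the copper transporter, had 231 ± 13.3 and 241 ± 13.3 (0.82), and ATP7B 49.3 ± 24.7 and 61.9 ± 29.4 (0.63). GSTP1 had 4210 ± 254 and 3722 ± 979 (0.41), ERCC1 358 ± 37.3 and 364 ± 81.8 (1), and CDKN1A 142 ± 59.2 and 74.1 ± 20.7 (0.093). VIM passed without OV90CisR1 replicate 1 (0.033) and GSTP1 without OV90CisR1 replicate 3 (0.035). CDKN1A passed without OV90 replicate 3 (0.007) or OV90CisR1 replicate 3 (0.045). Each was then lower in OV90CisR1. CDH1, which encodes E-cadherin, had 7 reads in the 3 OV90 libraries together, 0 in OV90CisR1 and 1 in OV90CisR2. SNAI2 had 5, 1 and 31 reads, and ABCB1 had 2 over all 9 libraries. These 3 genes lay below the filter and were not tested.

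Camera called 2 of 29 lists in OV90CisR1, both down. With an estimated correlation 0 were called, 2 having an unadjusted p under 0.05, and fry called 11. Among the lists that fry alone called were matrix proteases (adjusted p = 0.0093), fibroblast and endothelial markers (0.0093), mitochondrially encoded genes (0.032) and ABC transporters (0.032), up, and NF-kB cytokines (0.032), down. Of 52 ribosomal protein genes, 15 fell and none rose (26 fell adjusted over the list alone; camera adjusted p = 2.1e-07, and adjusted p = 0.5 with an estimated correlation). RPS27 fell from 4810 ± 245 to 2439 ± 523 normalised reads and RPS23 from 3042 ± 626 to 1768 ± 497. Of 30 glutathione and NRF2 target genes, 6 fell and none rose (1 rose and 6 fell adjusted over the list alone; camera adjusted p = 0.038, and adjusted p = 0.5 with an estimated correlation). FTH1, the ferritin heavy chain, fell from 3096 ± 505 to 1146 ± 495 and TXNRD1, thioredoxin reductase, from 486 ± 57.1 to 190.1 ± 60.6. The call of this list ended without OV90 replicate 1 (0.051) or OV90CisR1 replicate 2 (0.08). Of 14 platinum and copper transport genes, LRRC8D, a subunit of a volume-regulated anion channel, rose by 0.81 on the log2 scale, and COX17, a copper chaperone, fell by 1.44 (4 up and 1 down adjusted over the list alone; camera adjusted p = 0.35). Of 24 matrix proteases and inhibitors, 6 rose and 1 fell (7 and 2 adjusted over the list alone; camera adjusted p = 0.062). TIMP1, an inhibitor of matrix metalloproteinases, rose from 9.28 ± 1.5 to 38.2 ± 15.2 and MMP14 from 622 ± 68.9 to 1918 ± 453. Of 31 TGF-beta pathway genes, 7 rose and 4 fell (7 and 5 adjusted over the list alone; camera adjusted p = 0.5, median 0.05 and mean -0.04). BMP4 rose from 2992 ± 271 to 9200 ± 427 and BMP7 from 73.98 ± 9.24 to 188 ± 15.1, while TGFBR2 fell. The call for RPS23 was lost without any library except OV90CisR1 replicate 2 and OV90CisR2 replicate 2 (0.054 to 0.09) and that for TGFBR2 without OV90 replicates 1 or 2 or OV90CisR1 replicates 2 or 3 (0.055 to 0.12).

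Camera called no list for DNA damage in OV90CisR1, and fry called the p53 target and BCL2 family lists down (adjusted p = 0.032 and 0.035). Of 27 nucleotide excision repair genes 2 fell (2 rose and 4 fell adjusted over the list alone; camera adjusted p = 0.21). Of 38 homologous recombination and Fanconi anaemia genes 4 rose and 2 fell (6 and 2 adjusted over the list alone; camera adjusted p = 0.9). Of 18 mismatch repair and translesion synthesis genes 2 rose and 1 fell (4 and 3 adjusted over the list alone; camera adjusted p = 0.98). Median and mean differed in sign for the mismatch repair list (0.02 and -0.05) and for the homologous recombination list (-0.04 and 0.01). Of 27 p53 targets, 4 fell and none rose (5 fell adjusted over the list alone; camera adjusted p = 0.054), and of 22 BCL2 family genes and apoptosis regulators, 2 fell (9 at an unadjusted p under 0.05, 2 with edgeR and 5 with DESeq2, but 0 adjusted over the list alone; camera adjusted p = 0.054). PLK2 fell from 179 ± 79.7 to 43.8 ± 16.1 normalised reads and PHLDA3 from 36.9 ± 8.9 to 15.8 ± 2.89, the latter not without OV90 replicates 2 or 3 or OV90CisR1 replicates 1 or 2 (0.056 to 0.079). The p53 target list was called without OV90 replicate 3 (0.0055) or OV90CisR1 replicate 3 (0.023) and the BCL2 list without OV90 replicate 2 (0.019) or OV90CisR1 replicate 1 (0.044). The matrix protease list was called without OV90 replicate 1 (0.048) or OV90CisR1 replicate 3 (0.006), and the ABC transporter list without OV90CisR1 replicate 3 (0.039). The fibroblast marker list was called without OV90CisR1 replicate 3 (0.023), the hypoxia list without OV90 replicates 1 or 2 or OV90CisR1 replicate 3 (0.01 to 0.042), and the interferon and sterol lists without OV90 replicate 3 (0.0055 and 2.7e-05). OV90CisR1 replicate 3 stood apart, with medians of -0.35 over the BCL2 list and 0.24 over the sterol list against the other OV90CisR1 libraries.

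The second comparison asked how OV90CisR2 differed from OV90. CGA rose to 6132 ± 158 normalised reads (SD, n = 3), a log2 fold change of 9.29 ± 0.73 (SE; limma adjusted p = 2.6e-05). CRISPLD1 rose from 23.3 ± 4.7 to 782 ± 126, and FREM2 to 612 ± 28.5. TBX3, a T-box transcription factor (chromosome 12, 114670255 to 114684175), rose from 54.7 ± 14.4 to 1085 ± 78.6 and GJA1, which encodes connexin 43, from 82.3 ± 76.7 to 597 ± 77. ELAVL3, a neuronal RNA-binding protein, fell from 535 ± 155 to 118 ± 5.95, and BHLHE40 from 264 ± 44.6 to 70.1 ± 8.78. CCDC80 fell from 289.9 ± 114 to 83.7 ± 21.3, RRAGD from 391 ± 210 to 115 ± 18.1 and LOC124905143 from 267 ± 103 to 88.1 ± 5.45. In total 468 genes passed the threshold, 334 up and 134 down, and 317 of them changed at least 2-fold, 258 up and 59 down. The count was 878 with DESeq2, 287 with a replicate block, 3538 with quality weights and 3633 without OV90 replicate 3 and OV90CisR1 replicate 3. Rises made up 71.4% of the calls, 54.7% without these 2 libraries, 60.6% with DESeq2 and 54.4% with quality weights. The share was 86.5% and 85.8% without OV90 replicates 1 and 2, and 84.2%, 80.1% and 87% without OV90CisR2 replicates 1, 2 and 3. With 1 library left out the count was 223, 274 and 1312 without OV90 replicates 1, 2 and 3. It was 1071 without OV90CisR1 replicate 3, and 184, 196 and 177 without OV90CisR2 replicates 1, 2 and 3. The call for RRAGD was lost without any library except OV90 replicate 3 and OV90CisR1 replicate 3 (0.066 to 0.18), and that for LOC124905143 without OV90 replicates 1 or 2 or OV90CisR2 replicates 1, 2 or 3 (0.1 to 0.13). CCDC80 no longer passed without OV90 replicate 1 or OV90CisR2 replicates 1 or 3 (0.051 to 0.062).

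Of 15 tested epithelial markers in OV90CisR2, DSP rose from 0.667 ± 0.578, under 3 reads, to 52.2 ± 4.62 normalised reads (SD, n = 3) and KRT8, keratin 8, from 10.7 ± 13.5 to 68.5 ± 10.7, and none fell (2 and 0 adjusted over the list alone; camera adjusted p = 0.95, down). The list's median was -0.14, its mean 0.35 and fry's direction up. The KRT8 call was lost without any library except OV90 replicate 3 and OV90CisR1 replicate 3 (0.055 to 0.17). Of 37 mesenchymal markers, 4 rose and none fell (4 rose and 3 fell adjusted over the list alone; camera adjusted p = 0.042, and adjusted p = 0.44 with an estimated correlation). Fry called this list up (adjusted p = 0.00077). POSTN rose to 187 ± 33, and LUM, the matrix proteoglycan lumican, from 41.6 ± 13.1 to 426 ± 49.7. This camera call ended without OV90 replicates 1 or 3 or OV90CisR2 replicate 1 (0.055 to 0.07). Of 14 transcription factors of the transition, 2 rose, among them PRRX1 from 16.4 ± 7.21 to 50.8 ± 6.03 (2 up and 1 down adjusted over the list alone; camera adjusted p = 0.51, and fry adjusted p = 0.042, up). The call for PRRX1 was lost without OV90CisR2 replicates 1, 2 or 3 (0.098 to 0.12). VIM had 20070 ± 2760 normalised reads in OV90CisR2 (limma adjusted p = 0.17 against OV90), EPCAM 35.7 ± 2.91 (0.57) and CDH2 5.75 ± 1.49 (0.79). FN1 had 70.0 ± 8.4 (0.76), ZEB1 222 ± 26.3 (0.85) and AXL 108 ± 2.79 (0.84). SLC31A1 had 181 ± 23.5 (0.24), ATP7B 57.4 ± 17.8 (0.78), GSTP1 4762 ± 352 (0.64), ERCC1 257 ± 9.48 (0.19) and CDKN1A 96.9 ± 8.52 (0.52). VIM and ERCC1 passed without OV90CisR1 replicate 3 (0.0076 and 0.036), which enters this comparison only through the shared variance estimate. CDKN1A passed without OV90 replicate 3 (0.048). Each was lower in OV90CisR2.

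Of 27 Wnt and YAP targets in OV90CisR2, 3 rose and none fell (4 and 2 adjusted over the list alone; camera adjusted p = 0.25). DKK1, a secreted Wnt antagonist, rose from 4.07 ± 4.05 to 479 ± 64.2 normalised reads (SD, n = 3) and LEF1, a Wnt-responsive transcription factor, from 1.55 ± 1.39, under 3 reads, to 79.2 ± 16.1. Of 10 fibroblast and endothelial markers, 4 rose (4 adjusted over the list alone), POSTN and LUM most (camera adjusted p = 0.00012, and adjusted p = 0.44 with an estimated correlation). This list was fixed as a check for other cell types. It shares POSTN, LUM, COL3A1, ACTA2 and further members with the mesenchymal list, so calls of both are not independent. Of 25 collagens and matrix glycoproteins, COL4A2 and NID1 rose (3 up and 1 down adjusted over the list alone; camera adjusted p = 0.038, and adjusted p = 0.54 with an estimated correlation). Of 29 interferon-stimulated genes, IFIT1 fell from 53.3 ± 23.6 to 14.6 ± 2.19 and none rose (6 fell adjusted over the list alone; camera adjusted p = 0.00097, and adjusted p = 0.59 with an estimated correlation). Of 13 MHC genes, TAP1, a peptide transporter, fell (1 adjusted over the list alone; camera adjusted p = 0.0074, and adjusted p = 0.59 with an estimated correlation). Against the other OV90 libraries, OV90 replicate 3 had a median of -0.65 over the interferon list and -0.51 over the MHC list. Of 18 NF-kB cytokines and chemokines, CCL5 and BIRC3 fell (1 up and 6 down adjusted over the list alone; camera adjusted p = 0.014, and adjusted p = 0.53 with an estimated correlation). Of 31 hypoxia and glycolysis genes, 3 fell (5 adjusted over the list alone), DDIT4 from 81.97 ± 44 to 15.4 ± 1.25 and ENO2 from 407 ± 5.77 to 152 ± 9.35 (camera adjusted p = 0.014, and adjusted p = 0.59 with an estimated correlation). Of 27 unfolded protein and amino acid stress response genes, 2 fell, DDIT4 and VLDLR (5 adjusted over the list alone; camera adjusted p = 0.026, and adjusted p = 0.44 with an estimated correlation).

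No member passed with limma in 4 other lists that camera called in OV90CisR2. At an unadjusted p under 0.05, 9 cell cycle, 8 homologous recombination, 3 mitochondrially encoded and 5 sterol biosynthesis genes passed. With edgeR the counts were 0, 0, 1 and 1, and with DESeq2 1, 3, 2 and 2. With an estimated correlation camera called 0 lists, 3 having an unadjusted p under 0.05, and fry called 3. These 3 were the mesenchymal markers, the fibroblast and endothelial markers and the transcription factors of the transition, each up. Fry did not call the interferon, cell cycle and sterol lists (adjusted p = 0.27, 0.26 and 0.44). The 42 cell cycle and mitosis genes had a median log2 fold change of 0.34 (camera adjusted p = 8.5e-05, and adjusted p = 0.59 with an estimated correlation), and the 38 homologous recombination and Fanconi anaemia genes 0.16 (camera adjusted p = 0.011, and adjusted p = 0.54 with an estimated correlation). The 15 mitochondrially encoded genes had a median of 0.24 (camera adjusted p = 0.043, and adjusted p = 0.54 with an estimated correlation) and the 30 sterol biosynthesis genes -0.37 (camera adjusted p = 0.0074, and adjusted p = 0.59 with an estimated correlation). Adjusted over the list alone, 2 mitochondrially encoded genes rose and 0 members of the other 3 passed. OV90 replicate 3, which stood apart, had medians of 0.55 over the cell cycle list, 0.89 over the hypoxia list and -1.13 over the sterol list against the other OV90 libraries. Without it the hypoxia list turned up (0.79). Another fit, chosen after seeing the data, left out OV90 replicate 3 and OV90CisR1 replicate 3. In it 22 of 30 sterol genes fell and 30 of 42 cell cycle genes rose. Camera gave an adjusted p of 1.2e-14 for each list, and 0.14 and 0.24 with an estimated correlation. The interferon and MHC lists were still called (4.5e-07 and 7.3e-06), and the mitochondrial, collagen and hypoxia lists were not (0.14, 0.21 and 0.76). Left out singly, OV90 replicate 1 (0.26) or OV90 replicate 2 (0.096) ended the sterol call. The collagen call ended without OV90 replicate 3 (0.25) or OV90CisR2 replicate 1 (0.091). The mitochondrial call ended without OV90 replicate 3, OV90CisR1 replicate 2 or OV90CisR2 replicates 1 or 2 (0.051 to 0.26). Without OV90 replicate 1 the adjusted p was 0.054 for the MHC list, 0.063 for homologous recombination and 0.068 for the stress response, and camera called 7 lists in place of 12. The gene calls for IFIT1 and ENO2 were lost without OV90 replicates 1 or 2 or any OV90CisR2 library (0.081 to 0.13 and 0.067 to 0.092), as was that for TAP1 (0.11 to 0.13). COL4A2 no longer passed without OV90 replicate 1, OV90CisR1 replicate 1 or OV90CisR2 replicates 1, 2 or 3 (0.053 to 0.15), NID1 without OV90 replicate 2 or OV90CisR2 replicates 1, 2 or 3 (0.094 to 0.16) and CCL5 without OV90 replicates 1 or 2 or OV90CisR2 replicates 1 or 3 (0.069 to 0.085). BIRC3 and VLDLR no longer passed without any library except OV90 replicate 3 and OV90CisR1 replicate 3 (0.059 to 0.19 and 0.062 to 0.2). The p53 target list was not called (camera adjusted p = 0.93, median -0.13 and mean 0.12), and MDM2, a p53 target and inhibitor, rose from 277 ± 23.8 to 507 ± 19.4. The integrin list had a median of 0.15 and mean of 0.07 with a camera direction of down (adjusted p = 0.96). With limma 0 platinum and copper transport genes and 0 glutathione and NRF2 targets passed (camera adjusted p = 0.53 and 0.5), with 2 and 7 at an unadjusted p under 0.05, 0 and 1 with edgeR, and 0 and 2 with DESeq2.

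Changes against OV90 were then compared between the resistant lines. At least 2-fold rises were shared by 117 genes and falls by 24, and 5 genes changed in opposite directions. Independent lists of these sizes would share 10.7 rises and 1.79 falls. The Pearson correlation of log2 fold changes across genes, which are not independent replicates, was 0.508, against 0.5 in 100 simulations of unchanged groups with common controls. The covariance was 0.262 against 0.0594 simulated. Both changes use the same 3 OV90 libraries, which were too few to split. A shift particular to OV90 would enter both changes, so the shared counts do not tell it apart from changes of the resistant lines. Among genes with a mean above the median of tested genes, the largest shared rises were those of CGA, FREM2, CRISPLD1, the uncharacterised LOC112268009 and SCARNA9, a small Cajal body RNA. LOC112268009 rose from 67.7 ± 38.7 to 228 ± 32.1 and 206 ± 14.1. SCARNA9 rose from 99.2 ± 28.3 normalised reads to 280 ± 122 in OV90CisR1 and 375 ± 122 in OV90CisR2 (SD, n = 3). The shared falls past the rule's level filter were those of HOXB-AS3, from 517 ± 132 to 172 ± 32.2 and 189 ± 14.7, PNMA2, from 293 ± 23.5 to 105 ± 17.8 and 121 ± 18.8, BHLHE40 and LOC124905143. The genes that changed in opposite directions, chosen after their values were seen, were BICC1, CALCB, CDC42EP3 and LOC124901127, which fell in OV90CisR1 and rose in OV90CisR2, and S100A6, which did the reverse. With 1 library left out, the OV90CisR1 call was lost for CALCB (0.051 to 0.071) without OV90 replicates 2 or 3, OV90CisR1 replicates 1 or 2 or OV90CisR2 replicates 1 or 3. It was lost for CDC42EP3 (0.054 to 0.1) without OV90 replicates 1 or 2, OV90CisR1 replicate 2 or OV90CisR2 replicates 1, 2 or 3, and for S100A6 (0.068 to 0.091) without OV90 replicates 1 or 3 or OV90CisR1 replicates 1 or 2. The OV90CisR2 call was lost for CDC42EP3 (0.084 to 0.092) without OV90CisR2 replicates 1, 2 or 3, and for BICC1 (0.055 to 0.089) without OV90 replicates 1 or 2 or OV90CisR2 replicates 1, 2 or 3. The fall of LOC124905143 was lost in OV90CisR1 without any library except OV90 replicate 3 and OV90CisR1 replicate 2 (0.05 to 0.12) and in OV90CisR2 without OV90 replicates 1 or 2 or OV90CisR2 replicates 1, 2 or 3 (0.1 to 0.13), and the rise of LOC112268009 in OV90CisR2 without OV90 replicate 2 or OV90CisR2 replicates 1, 2 or 3 (0.059 to 0.093). The shared total of 141 was 272 without OV90 replicate 3, 83 without OV90 replicate 1, and 83, 82 and 83 without OV90CisR2 replicates 1, 2 and 3. At least 2-fold changes in OV90CisR1 with no call in OV90CisR2 numbered 850, of which 356 differed past the threshold between the resistant lines. For the reverse, 106 of 159 did.

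**Figure D2:**
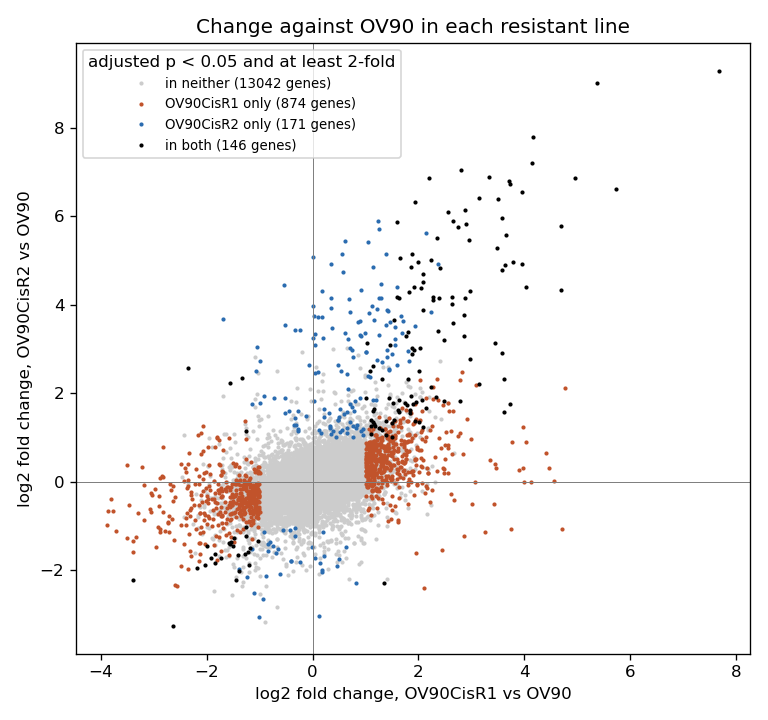
Log2 fold change against OV90 of each of the 14233 tested genes in OV90CisR1 (horizontal axis) and OV90CisR2 (vertical axis). Colours mark genes past the threshold and changed at least 2-fold in OV90CisR1 alone (874), OV90CisR2 alone (171), both (146) or neither (13042).

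The third comparison set OV90CisR2 directly against OV90CisR1. TBX3 was higher in OV90CisR2 by 4.13 ± 0.20 (SE) on the log2 scale (limma adjusted p = 2.4e-06; n = 3 per group), and BEX1, DLX5, S100A10 and CRISPLD1 were higher by 2.95, 2.84, 2.83 and 2.78. ALCAM was lower, with a log2 fold change of -3.14 ± 0.14 (limma adjusted p = 1.3e-06), as were LOC105369949, GCG, which encodes proglucagon, SLIT2 and CLDN11, with -2.53, -2.47, -2.35 and -2.30. FN1 was higher in OV90CisR2 by 2.24 ± 0.26 (limma adjusted p = 0.00066). In total 1433 genes passed, 735 higher and 698 lower, and 673 of them differed at least 2-fold, 379 higher and 294 lower. The count was 875 with a replicate block, 4226 with quality weights and 3750 without OV90 replicate 3 and OV90CisR1 replicate 3. With single libraries left out it was 2327 without OV90 replicate 3, 952 without OV90CisR1 replicate 1, and 450, 663 and 442 without OV90CisR2 replicates 1, 2 and 3. Of the remaining panel genes, none passed, and VIM, at 0.05 ± 0.30 (adjusted p = 0.93), turned in sign without the 2 libraries left out above. Without OV90CisR1 replicate 3, GSTP1 was higher (0.0091) and ERCC1 lower (0.0095).

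Of 37 mesenchymal markers, 10 were higher and 3 lower in OV90CisR2 than in OV90CisR1 (10 and 4 adjusted over the list alone; camera adjusted p = 0.36, and fry adjusted p = 0.0091, up). ACTA2 had 2.94 ± 3.45 and 28.6 ± 6.13 normalised reads (SD, n = 3), and LUM 79.02 ± 51.4 and 426 ± 49.7. SPARC had 12.1 ± 4.2 and 0.926 ± 0.0844, the latter under 3 reads, and WNT5A 1255 ± 15.2 and 361 ± 20. Of 15 epithelial markers, DSP and CD24 were higher and LSR lower (5 and 3 adjusted over the list alone; camera adjusted p = 0.73). Of 14 transcription factors of the transition, 3 were higher and ZEB2 lower (3 and 2 adjusted over the list alone; camera adjusted p = 0.27, and fry adjusted p = 0.0077, up). GSC had 1.08 ± 1.06, under 3 reads, and 9.99 ± 3.15, ETS1 6.65 ± 4.87 and 31.98 ± 7.22, and ZEB2 402 ± 53.3 and 196 ± 21.6. These calls were lost for CD24, ETS1 and WNT5A without any OV90CisR2 library (0.062 to 0.094, 0.07 to 0.12 and 0.056 to 0.066). They were lost for GSC and ZEB2 without any of these or OV90CisR1 replicate 1 (0.063 to 0.11 and 0.055 to 0.11), and for LSR without OV90 replicates 1 or 2, OV90CisR1 replicate 2 or OV90CisR2 replicates 1, 2 or 3 (0.066 to 0.16).

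Camera called 8 lists between the resistant lines, 6 higher and 2 lower in OV90CisR2, and 0 with an estimated correlation, where 4 had an unadjusted p under 0.05. Fry called 9. Of 52 ribosomal protein genes, 9 were higher (25 adjusted over the list alone; camera adjusted p = 9.9e-09, and adjusted p = 0.3 with an estimated correlation), among them RPS27 and RPS23. Of 42 cell cycle genes, 6 were higher (12 adjusted over the list alone; camera adjusted p = 1.5e-05, and adjusted p = 0.55 with an estimated correlation). RRM2, the small subunit of ribonucleotide reductase, had 1598 ± 176 and 2891 ± 129 normalised reads and TYMS, thymidylate synthase, 1111 ± 202 and 1855 ± 249 (SD, n = 3). Of 24 matrix proteases and inhibitors, MMP24 was higher and 6 were lower (2 and 9 adjusted over the list alone; camera adjusted p = 0.016, and adjusted p = 0.3 with an estimated correlation). MMP3 had 138 ± 26.9 and 10.8 ± 4.05 and MMP1 62.2 ± 2.98 and 13.4 ± 1.01. Of 27 Wnt and YAP targets, 7 were higher (9 adjusted over the list alone; camera adjusted p = 0.016, and adjusted p = 0.32 with an estimated correlation), LEF1 and DKK1 most. Against the other OV90CisR1 libraries, OV90CisR1 replicate 3 had a median of -0.55 over this list, in the direction of the call. Without it and OV90 replicate 3 the camera adjusted p was 0.049. Of 27 p53 targets, 4 were higher (8 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.016, and adjusted p = 0.32 with an estimated correlation). EDA2R had 1.4 ± 1.21 and 15.8 ± 4.11 and the death receptor FAS 0.719 ± 0.624 and 10.7 ± 4.97, both under 3 reads in OV90CisR1. Of 31 TGF-beta pathway genes, CCN2 was higher and 7 were lower, BMP4 and INHBA most (1 and 7 adjusted over the list alone; camera adjusted p = 0.02, and adjusted p = 0.32 with an estimated correlation). Of 30 glutathione and NRF2 targets, 4 were higher, FTH1 and TXNRD1 most (7 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.033, and adjusted p = 0.3 with an estimated correlation). Of 10 fibroblast and endothelial markers, 4 were higher and COL3A1 was lower (4 and 1 adjusted over the list alone; camera adjusted p = 0.049, and adjusted p = 0.44 with an estimated correlation). Of 14 platinum and copper transport genes, COX17 was higher and 3 were lower, among them LRRC8D (1 and 6 adjusted over the list alone; camera adjusted p = 0.11).

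Some of the list calls between the resistant lines depended on single libraries. Without OV90CisR1 replicate 1 the adjusted p was 0.091 for the TGF-beta list and 0.066 for matrix proteases, and 5 lists were called. The glutathione call ended without OV90CisR1 replicate 2 (0.073) or OV90CisR2 replicate 3 (0.051) and the fibroblast call without OV90 replicates 2 or 3, OV90CisR1 replicate 1 or OV90CisR2 replicates 1 or 3 (0.051 to 0.078). The ABC transporter, MHC and stress response lists were called lower without OV90 replicate 3 (0.044 for each) or OV90CisR1 replicate 3 (0.0047, 0.001 and 0.018), and the sterol list without OV90 replicate 3 (0.035). Gene calls for RRM2, MMP24, FTH1 and COX17 were lost without any OV90CisR2 library (0.052 to 0.07, 0.07 to 0.092, 0.061 to 0.12 and 0.06 to 0.13). TYMS no longer passed without OV90CisR1 replicate 2 or OV90CisR2 replicates 1, 2 or 3 (0.058 to 0.14), nor INHBA without OV90CisR1 replicate 2 or OV90CisR2 replicates 2 or 3 (0.052 to 0.06). RPS23 no longer passed without OV90 replicate 2, OV90CisR1 replicates 1 or 3 or OV90CisR2 replicates 1 or 3 (0.051 to 0.15), nor TXNRD1 without any library except OV90 replicate 3 and OV90CisR1 replicate 1 (0.055 to 0.17). LRRC8D no longer passed without OV90CisR1 replicate 1 or OV90CisR2 replicates 1 or 3 (0.053 to 0.086), EDA2R without OV90CisR2 replicate 1 (0.055) or OV90CisR2 replicate 3 (0.051) and FAS without OV90CisR2 replicate 1 (0.079). Median and mean differed in sign for the receptor tyrosine kinase list (-0.21 and 0.09; camera adjusted p = 0.86), the ovarian lineage list (-0.06 and 0.26; 0.98) and the NF-kB list (0.01 and -0.12; 0.81).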

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

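The limma test of the difference between the resistant lines was planned, and the 5 genes that changed in opposite directions were chosen after their values were seen. The results here are 65 changes against OV90 of named genes that differed between OV90CisR1 and OV90CisR2, with 3 libraries per line. Because OV90 is common to both changes, their difference is the log2 difference OV90CisR2 minus OV90CisR1, given in parentheses, and its limma adjusted p ran from 1.3e-06 to 0.047. No technical or biological explanation was tested for these differences, and cisplatin was in the medium of both lines.

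Past the threshold in opposite directions were LOC124901127 (4.92), CDC42EP3 (3.8), CALCB (3.68), S100A6 (-3.64) and BICC1 (2.41). Of these S100A6, a calcium-binding protein, rose in OV90CisR1 and fell in OV90CisR2, and the others did the reverse. Not each direction rests on a call that holds with 1 library left out. In OV90CisR1 the call was lost for CALCB (0.051 to 0.071) without OV90 replicates 2 or 3, OV90CisR1 replicates 1 or 2 or OV90CisR2 replicates 1 or 3. It was lost for CDC42EP3 (0.054 to 0.1) without OV90 replicates 1 or 2, OV90CisR1 replicate 2 or OV90CisR2 replicates 1, 2 or 3. S100A6 (0.068 to 0.091) did not pass without OV90 replicates 1 or 3 or OV90CisR1 replicates 1 or 2. In OV90CisR2 the call was lost for CDC42EP3 (0.084 to 0.092) without OV90CisR2 replicates 1, 2 or 3. BICC1 (0.055 to 0.089) did not pass there without OV90 replicates 1 or 2 or OV90CisR2 replicates 1, 2 or 3.

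Rises in both lines differed in size for DKK1 (4.25), DSP (3.42), ALCAM (-3.14), CRISPLD1 (2.78), PDGFC (2.1), POSTN (1.93) and JAG1 (-1.29). They include the Wnt antagonist DKK1, the desmosomal protein DSP, the adhesion molecule ALCAM and the matrix protein POSTN. ELAVL3 (-1.26), a neuronal RNA-binding protein, fell in both lines and lay lower in OV90CisR2. The OV90CisR1 call was lost for PDGFC whichever of the 9 libraries was left out (0.058 to 0.096) and for DSP (0.057 to 0.11) without any library except OV90CisR1 replicate 3. ELAVL3 did not pass there without OV90 replicate 1 (0.081) or OV90 replicate 2 (0.069).

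Among genes past the threshold in OV90CisR1 alone, a rise and a lower level in OV90CisR2 were found for WNT5A (-1.79), BMP4 (-1.74), ABCA1 (-1.57), MERTK (-1.43), IFITM2 (-1.41), MMP14 (-1.41), ITGAV (-1.35), COL3A1 (-1.31), BMP7 (-1.12), HEY1 (-1.02), SDF2L1 (-1.02), LRRC8D (-0.84), SREBF2 (-0.67) and B2M (-0.61). A fall and a higher level in OV90CisR2 were found for ACTA2 (3.34), BEX1 (2.95), S100A10 (2.83), CD24 (2.41), PLK2 (2.34), FN1 (2.24), ITGA11 (2.24), CCN2 (2.12), ITGA1 (2.11), SPECC1 (2.1), ADD2 (1.9), FHL1 (1.79), NDRG1 (1.59), STARD4 (1.29), COX17 (1.26), FTH1 (1.2), RPS27 (1.2), DDR2 (1.17), RAD51C (1.07), ALDH3A2 (0.95), RPS23 (0.87), PSMB9 (0.82), TXNRD1 (0.81), PMVK (0.75), TYMS (0.75) and USP1 (0.51). The first group holds the secreted ligands WNT5A, BMP4 and BMP7 and the Notch target HEY1, and the other fibronectin (FN1), smooth muscle actin (ACTA2), integrin subunits and the YAP target CCN2. USP1 lost its call against OV90 whichever of the 9 libraries was left out (0.061 to 0.12). Only OV90CisR1 replicate 3 could be left out with the call kept for ACTA2 (0.069 to 0.1) and PMVK (0.063 to 0.11), only OV90CisR1 replicate 2 for RAD51C (0.062 to 0.097), and only OV90CisR1 replicate 2 or OV90CisR2 replicate 2 for RPS23 (0.054 to 0.09). ITGA1 (0.052 to 0.12) did not pass without OV90 replicates 1 or 2, OV90CisR1 replicates 2 or 3 or OV90CisR2 replicates 1 or 3. The rise of B2M (0.053 to 0.06) was lost without OV90 replicates 1 or 2 or OV90CisR1 replicates 1 or 2. The calls of CD24 (0.076 and 0.059) and STARD4 (0.067 and 0.057) were lost without OV90 replicate 1 or OV90 replicate 2, those of WNT5A (0.052) and TYMS (0.054) without OV90 replicate 1, and that of DDR2 (0.063) without OV90 replicate 2. In OV90CisR2, the threshold was passed without OV90 replicate 3 by BEX1 (0.014), PSMB9 (0.029) and WNT5A (0.011).

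Among genes past the threshold in OV90CisR2 alone, a rise and a higher level than in OV90CisR1 were found for LEF1 (4.61), TBX3 (4.13), LIN28B (2.75), LUM (2.75), GJA1 (2.56), COL4A2 (2.04) and MDM2 (0.82). A fall and a lower level were found for CCL5 (-2.04), IFIT1 (-1.91), CCDC80 (-1.77), INHBA (-1.69) and MMP10 (-1.31). The rises include the transcription factors LEF1 and TBX3 and the RNA-binding protein LIN28B, and the falls the chemokine CCL5 and the interferon-stimulated gene IFIT1. With 1 library left out, the call against OV90 was lost for LIN28B (0.051 to 0.074) without OV90CisR2 replicates 1, 2 or 3, and for COL4A2 (0.053 to 0.15) without OV90 replicate 1, OV90CisR1 replicate 1 or OV90CisR2 replicates 1, 2 or 3. Among the falls it was lost for IFIT1 (0.081 to 0.13) without OV90 replicates 1 or 2 or OV90CisR2 replicates 1, 2 or 3, and for CCL5 (0.069 to 0.085) without OV90 replicates 1 or 2 or OV90CisR2 replicates 1 or 3. CCDC80 (0.051 to 0.062) did not pass without OV90 replicate 1 or OV90CisR2 replicates 1 or 3. In OV90CisR1, the threshold was passed by COL4A2 (0.018) and GJA1 (0.0017) without OV90 replicate 3 and by LUM (0.003) without OV90CisR1 replicate 3.

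Levels near 3 reads make the size of some differences depend on the pseudocount. In OV90CisR1, ITGA11 had 0 reads, and ACTA2, LEF1, LIN28B and LOC124901127 had means of 2.94, 2.48, 3.26 and 2.47 normalised reads. CALCB, CDC42EP3 and CD24 had means of 3.59, 3.55 and 3.5 there. In OV90CisR2, CCL5 had a mean of 2.39 normalised reads.

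With 1 library left out in turn, 41 of the 65 differences passed each time and 24 were lost at least once. The adjusted p rose past 0.05 for ABCA1 (0.076 to 0.12), B2M (0.068 to 0.12), ITGA11 (0.06 to 0.11), JAG1 (0.082 to 0.11), LIN28B (0.053 to 0.1) and PMVK (0.054 to 0.07) without OV90CisR1 replicates 1 or 2 or OV90CisR2 replicates 1, 2 or 3, and for CCL5 (0.055 to 0.16) without any library except OV90 replicate 1 and OV90 replicate 3. Calls were lost for CD24 (0.062 to 0.094), COX17 (0.06 to 0.13), FTH1 (0.061 to 0.12) and WNT5A (0.056 to 0.066) without OV90CisR2 replicates 1, 2 or 3, and for DDR2 (0.062 to 0.14) without OV90CisR1 replicates 1 or 3 or OV90CisR2 replicates 1, 2 or 3. The test was also not passed for INHBA (0.052 to 0.06) without OV90CisR1 replicate 2 or OV90CisR2 replicates 2 or 3, and for ITGA1 (0.055 to 0.12) without OV90CisR1 replicates 2 or 3 or OV90CisR2 replicates 1, 2 or 3. The adjusted p rose past 0.05 for LRRC8D (0.053 to 0.086) and STARD4 (0.052 to 0.1) without OV90CisR1 replicate 1 or OV90CisR2 replicates 1 or 3, and for PSMB9 (0.064 to 0.16) without OV90 replicate 2, OV90CisR1 replicate 2 or OV90CisR2 replicates 1, 2 or 3. Calls were lost for RAD51C (0.057 to 0.065) and SDF2L1 (0.077 to 0.089) without OV90CisR2 replicates 1 or 3, and for RPS23 (0.051 to 0.15) without OV90 replicate 2, OV90CisR1 replicates 1 or 3 or OV90CisR2 replicates 1 or 3. The test was also not passed for SREBF2 (0.053 to 0.14) without any library except OV90 replicate 2 and OV90 replicate 3, and for TXNRD1 (0.055 to 0.17) without any library except OV90 replicate 3 and OV90CisR1 replicate 1. The adjusted p rose past 0.05 for TYMS (0.058 to 0.14) without OV90CisR1 replicate 2 or OV90CisR2 replicates 1, 2 or 3, and for USP1 (0.052 to 0.12) without OV90 replicate 1, OV90CisR1 replicates 1 or 2 or OV90CisR2 replicates 1, 2 or 3.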

How the results depend on the processing

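TMM scaling, quality weights, removal of the GC trend and omission of OV90 replicate 3 and OV90CisR1 replicate 3, called the 2 libraries below, were chosen after seeing the data. Planned median-of-ratios scaling was not run, as the deposited values are scaled this way. Numbers did not pair the libraries (2 of 18 had their best correlate under their own number), so the replicate block is given here only as a number of calls. Over the alternatives, named genes kept direction and side of the threshold in 4913 cases, lost the call in 703, gained one in 41 and reversed in 1, and lists in 1183, 70, 50 and 2. Of 206 named calls, 103 held without any 1 library. Fits of only the groups compared gave 771 genes for OV90CisR1 against OV90, 504 at least 2-fold, and 88 shared genes, while OV90CisR2 against OV90 rose to 683 and OV90CisR2 against OV90CisR1 to 1731. The replicate block gave 287 genes for OV90CisR2 against OV90 and 875 between the resistant lines, and 4 lists in OV90CisR1. DESeq2 gave 878 genes for OV90CisR2 against OV90, and a filter of 5 per 1e+06 gave 200 at least 2-fold, with fewer genes tested. Without the 2 libraries, 3901, 3633 and 3750 genes were called in the order of the report, 935 at least 2-fold in OV90CisR2, 393 shared, and 7 lists in OV90CisR1. Of the 2252, 468 and 1433 genes, 2011, 468 and 1425 were among these. Quality weights gave 4220, 3538 and 4226 genes, 938 at least 2-fold in OV90CisR2 and 1089 between the resistant lines, and 417 shared. An estimated correlation gave 0 lists in each comparison, where it had 2, 3 and 4 at an unadjusted p under 0.05, and fry gave 11 and 3 against OV90. Quantile scaling gave 5 lists and removal of the GC trend 6 in OV90CisR1. VIM between the resistant lines turned to -0.388 without the 2 libraries (adjusted p = 0.03; 0.03 to 1 over the alternatives), and the hypoxia list in OV90CisR2 turned up (adjusted p = 0.76). With 1 library left out, OV90CisR1 against OV90 gave 939 to 2467 genes, 565 to 1159 at least 2-fold, and 1 to 7 lists. OV90CisR2 against OV90 gave 177 to 1312 genes, 164 to 601 at least 2-fold, and 7 to 12 lists, with the hypoxia list at an adjusted p of 0.00013 to 0.79. OV90CisR2 against OV90CisR1 gave 442 to 2327 genes, 322 to 867 at least 2-fold, and 5 to 11 lists, and shared genes numbered 82 to 272. The extremes came without OV90 replicate 1 (939 and 7 lists) or OV90 replicate 3 (2467, 1312, 2327, 272 and 0.79), OV90CisR1 replicates 1, 2 or 3 (5, 1 and 7 lists), or OV90CisR2 replicates 2 or 3 (82, 177 and 442). A library outside a comparison acts on it only through the variance estimate shared by all 9 libraries. This holds for OV90CisR1 replicate 3 in OV90CisR2 against OV90 (468 genes with it and 1071 without, median log2 fold change 0.004 in both). It also holds for OV90 replicate 3 between the resistant lines (1433 and 2327 genes). Apart from these and the fewer genes under that filter, the cause was not tested. Depth limits genes such as CDH1 and ABCB1, with 8 and 2 reads over all libraries, and SNAI2, with 31 of its 37 reads in OV90CisR2, was below the filter and not tested.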

Other observations

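The tests of GC content and of RNA of other cells in OV90CisR1 replicate 3, the tests on chromosome 13 and the splits of the samples for counts of genes were chosen after the results were seen, as were the genes named in the next paragraph.

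Transcripts of peptide hormones were abundant while several markers of epithelial ovarian carcinoma gave few or no reads. Of 41 epithelial markers 15 passed the filter on low values, and of 32 ovarian carcinoma lineage markers 6 did, with medians over the lists of 1.61 and 0.334 normalised reads in OV90. Others were detected, with EPCAM at 44.9 ± 6.77, MUC1 at 129 ± 22.3 and LSR at 549 ± 24.5 normalised reads in OV90 (SD, n = 3). GCG, which encodes proglucagon, had 13135 reads over the 3 OV90 libraries, 39023 in OV90CisR1 and 7032 in OV90CisR2, and PRL, which encodes prolactin, had 2247, 7548 and 3209. TWIST1, a transcription factor of mesenchymal cells, had 11829, 10146 and 9010 reads, and COL3A1, a fibrillar collagen, 9804, 24794 and 11184. PAX8, a lineage transcription factor of ovarian carcinoma, had 0, 1 and 0 reads, MUC16, which encodes the antigen CA125, 0, 1 and 0, and WT1 4, 5 and 25. MSLN had 1, 0 and 1 reads, and WFDC2, CLDN3 and KRT19 had 0 in each library, which allows up to 3 reads. KRT7 had 0, 5 and 0 reads, KRT18 3, 16 and 0, and KRT8 35, 48 and 221. The levels of both kinds leave the labelled identity of the cells in doubt, which was not tested, and with it what a change of epithelial or mesenchymal markers means.

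Other lists held changes in 1 or both resistant lines. Of 19 stem cell and aldehyde dehydrogenase genes, 3 rose and 3 fell in OV90CisR1 (4 and 4 adjusted over the list alone; camera adjusted p = 0.98) and 3 rose in OV90CisR2 (3 up and 1 down adjusted over the list alone; camera adjusted p = 0.33). JAG1, a Notch ligand, rose from 27.2 ± 11.8 to 323 ± 70.5 normalised reads in OV90CisR1 and 130 ± 12.8 in OV90CisR2 (SD, n = 3). HEY1, a Notch target, rose to 1589 ± 308 in OV90CisR1 from 663 ± 107, and ALDH3A2 fell from 474 ± 43 to 204 ± 37.3. Fry gave the direction up in OV90CisR1 for this list, whose median was -0.20. Of 31 receptor tyrosine kinases and ligands, 6 rose and 2 fell in OV90CisR1 (7 and 4 adjusted over the list alone; camera adjusted p = 0.51, and fry adjusted p = 0.044, up; median 0.12 and mean -0.03). In OV90CisR2, 1 rose and 1 fell (2 and 1 adjusted over the list alone; camera adjusted p = 0.58, median -0.01 and mean 0.06). PDGFC, a platelet-derived growth factor, rose from 6.77 ± 0.453 to 15.1 ± 2.68 and 68.5 ± 17.3, with the OV90CisR1 call lost whichever of the 9 libraries was left out (0.058 to 0.096), and FGF2 fell from 194 ± 91 to 64.5 ± 18.9 in OV90CisR1. Of 14 integrins, 3 rose and 4 fell in OV90CisR1 (4 and 5 adjusted over the list alone; camera adjusted p = 0.98). Among them ITGAV rose from 486 ± 67.1 to 1088 ± 26.8. With limma 0 integrins passed in OV90CisR2, against 4 at an unadjusted p under 0.05, 0 with edgeR and 1 with DESeq2. Of 25 collagens and matrix glycoproteins, 6 rose and 2 fell in OV90CisR1 (9 and 3 adjusted over the list alone; camera adjusted p = 0.28), HSPG2, which encodes perlecan, from 52.5 ± 13.3 to 183 ± 58.9.

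Of 21 ABC transporters, 5 rose and 1 fell in OV90CisR1 (7 and 2 adjusted over the list alone; camera adjusted p = 0.18) and 1 rose and 1 fell in OV90CisR2 (1 and 1 adjusted over the list alone; camera adjusted p = 0.93). ABCA5 rose from 15.1 ± 1.24 to 80.8 ± 17.9 normalised reads in OV90CisR1 and 59.9 ± 7.66 in OV90CisR2 (SD, n = 3), and ABCA1, which exports cholesterol, rose from 26.1 ± 15.2 to 81.2 ± 12 in OV90CisR1. Of 27 unfolded protein and amino acid stress response genes, 4 rose and 5 fell in OV90CisR1 (5 and 7 adjusted over the list alone; camera adjusted p = 0.93). SDF2L1, a chaperone of the endoplasmic reticulum, rose from 371 ± 90.8 to 851 ± 186, and PSAT1, an enzyme of serine synthesis, fell from 458 ± 147 to 136 ± 44.9. Of 27 Wnt and YAP targets, 3 rose and 5 fell in OV90CisR1 (3 and 7 adjusted over the list alone; camera adjusted p = 0.22), CCN2 from 529 ± 26.7 to 159 ± 33.5. Of 29 interferon-stimulated genes, 2 rose and 4 fell in OV90CisR1 (3 and 5 adjusted over the list alone; camera adjusted p = 0.26), with IFITM2 at 60.8 ± 3.18 in OV90 and 146 ± 47.5 in OV90CisR1. Against the other OV90CisR1 libraries, OV90CisR1 replicate 3 had medians of -0.55 over the Wnt and YAP list, -0.47 over the stem cell list and -0.39 over the stress response list.

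In OV90CisR1 replicate 3, 224 of 10402 genes lay more than 2 log2 units below the other libraries of the group and 0 as far above, and 98.7% of the 224 were below all other 8 libraries. Lower read depth would not give this, as the library held 5825708 reads against 6211177 and 6096939 in OV90CisR1 replicates 1 and 2. Thinning a library of the group to the same read total put 0 genes as far below. With totals this close that outcome was fixed in advance, so the thinning adds nothing to the totals. RNA of other cells mixed in could put genes as far above, and 0 of the 10402 genes compared were. The genes compared were chosen with a log2 level of 6, so genes with low values in these cells may be missing. The 0 was also known before this test was chosen. It therefore cannot decide on RNA of other cells, which stays open. Deviations rose with the GC content of the transcript end across genes (Spearman rho 0.421, genes not being independent replicates), with 10.7% of 337 genes of at most 20% GC far below and 0.436% of those between 50 and 60%. In the other libraries rho ran from -0.383 in OV90CisR1 replicate 2 to 0.273 in OV90CisR2 replicate 2, where 2 genes lay as far below. Each library was compared with the rest of its group, so the values of OV90CisR1 replicates 1 and 2 depend in part on replicate 3. A bias against AT-rich transcript ends is a candidate explanation for part of the pattern. Once the trend was removed, 149 of 213 genes stayed as far below (median -2.49 before and -2.25 after). These genes were picked for their low values, and the trend is an average over genes at annotated transcript ends. The removal therefore cannot decide whether the bias is the whole cause. RNA degradation and a biological difference between the cultures were not tested and stay open.

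Genes of chromosome 13 between 30 and 40 Mb, a window chosen after its values were seen and home to FREM2 and POSTN, were higher in OV90CisR2 than in OV90, with a median log2 fold change of 0.60 over 30 genes (camera adjusted p = 2.9e-08). GC content as the cause is argued against by a median of 0.65 with the trend removed, and OV90CisR2 replicate 2 alone by 0.51 without this library. Of the window's genes, 90% had a log2 fold change above 0, so most of the measured values were positive. This does not settle whether a few strongly changed genes, such as POSTN (5.58) and FREM2 (4.34), drew the window out, because its choice favours a high share. Gain of a chromosome segment stays open, because the share above the median of all genes, also 90%, restates how the window was chosen and does not test it. In OV90CisR1 the median of the window was 0.59, with 73.3% of genes above the median (camera adjusted p = 0.0054). No DNA was measured, and shared regulation of neighbouring genes was not tested and stays open.

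Of 277 windows of 10 Mb with at least 10 genes, camera called 10 in OV90CisR1 and 29 in OV90CisR2 against OV90 and 10 between the resistant lines, and at most 0 in 20 permutations of gene positions. With the GC trend removed these counts were 4, 29 and 7, and without OV90CisR2 replicate 2 they were 10, 31 and 12. Permuting positions breaks any correlation between neighbouring genes, so the permutations do not limit false calls from shifts that neighbours share. The windows were tested with the preset correlation of 0.01 only, not with an estimated one. In OV90CisR2 the called windows include chromosome 6 between 120 and 130 Mb (median 0.64) and between 80 and 90 Mb (0.29), which holds CGA, and chromosome 14 between 70 and 80 Mb (-0.23). All called windows of chromosome 6 there were higher, and they lay between 0 and 20, 80 and 90, and 100 and 170 Mb. Those of chromosome 14 were all lower and lay between 30 and 40, 50 and 80, and 90 and 110 Mb. The cause of these runs was not tested. In OV90CisR1 the called windows include chromosome 18 between 0 and 10 Mb (-0.61).

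Other splits of the 6 libraries of each comparison into 3 and 3 were tested with limma. The real split gave 2252, 468 and 1433 genes for OV90CisR1 and OV90CisR2 against OV90 and OV90CisR2 against OV90CisR1, and the highest other gave 0 in each, so 1 of 10 splits reached the real count. At an unadjusted p under 0.05 the real splits gave 4777, 2515 and 3999 genes and the highest others 1364, 1020 and 878. For gene lists, the real splits gave 2, 12 and 8 lists, the highest others 7, 8 and 2, and 10, 1 and 1 of 10 splits reached the real count. These 10 splits are too few for a share under 0.05. Other splits for OV90CisR1 against OV90 called up to 7 lists, so the 2 of the real split do not stand out. Why they called more was not tested. The 141 genes shared by both resistant lines were reached in 2 of 100 splits of the 9 libraries, the real grouping being 1 of these 2. Mixed groups give few calls whatever the cause, so the splits do not test whether the lines share changes, and no conclusion is drawn from them. The highest other, 228, had the 3 OV90CisR1 libraries as its reference group, and the next gave 34. That split kept 1 line whole, so it is not free of real differences between the lines. A line kept whole as the reference can thus give more shared genes than OV90 did.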
